A study of Drosophila melanogaster with 2 samples.

How the data were processed

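Binding of the CG30020 product was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in transgenic Drosophila melanogaster that carried CG30020 fused at its C terminus to enhanced green fluorescent protein. Per the labels, an antibody against GFP was used on whole embryos of mixed sex aged 0 to 24 h, and the fragments were 200 to 800 bp long. The labels give 1 group with 2 biological replicates, numbered 2 and 3, so no comparison between groups was possible and p-values below compare positions or genes, not conditions.

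The authors deposited 4 peak lists on assembly dm6. Each replicate's list and the pooled list were called against 1 control alignment, and the authors derived the fourth list, thresholded by irreproducible discovery rate (IDR), from those lists, per the notes deposited with the peak files. The aligner, the peak caller and their versions are not given in the sources used here, and the control alignment was not analysed here. The signal value of each peak is as the authors deposited it, on a scale that is not stated, so it was used only to rank peaks or to divide by the median of the same list. The deposited −log10 q value was capped, and all 5048 IDR peaks held the same value of 4.23, so q did not rank them. The summit is the deposited offset from the peak start. It lay at or past the interval's end in 1 IDR peak. Read depth per library is unknown from these lists. Each relaxed list holds exactly 30000 peaks, so its length says nothing about depth.

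The genome sequence was Release 6 (the sequence of dm6) and the gene models were those of Ensembl release 115, whose chromosome lengths contain every peak. Transposable element entries were left out of the TSSs and the annotation classes. Each summit was put in 1 of 7 exclusive classes, in the order promoter (within 500 bp of a TSS), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. Class shares were set against 10000 random placements on called bases of the same chromosome, and peaks per arm against 10000 random placements over the 7 chromosomes. Replicate overlap (at least 1 bp) was set against 1000 random placements of the other replicate's intervals. These permutation tests were two-sided, and the smallest p they can give is 0.0002 for 10000 placements and 0.002 for 1000.

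A protein-coding gene counted as bound when an IDR summit lay within 500 bp of any of its TSSs. For 25 gene lists, fixed before the data were examined, the share of bound members was compared with all other protein-coding genes on 2L, 2R, 3L, 3R, 4 and X by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 25 lists. Symbols in a list that the annotation no longer used were matched through synonyms, a step added after the peaks had been seen. Divergent promoters were compared with the others by Fisher's exact test, planned as two-sided; its p was too small for the computer to hold, so the logarithm of the one-sided p is given in its place. A total of 20 consensus motifs, also fixed in advance, and all 2080 strand-collapsed 6-mers were searched within 50 bp of each summit and in a window of the same width 300 bp away on a random side, and compared by exact McNemar tests with Benjamini-Hochberg adjustment. Windows at the same offset from the TSSs of unbound genes were compared with promoter summits by Fisher's exact test. GC content was compared by sign-flip permutation, and median log2 signal by permutation of labels, each with 100000 resamples, for which the smallest p is 1e-05.

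Genes were named by a rule set before the data were examined. It took the nearest TSS of the 20 strongest IDR peaks. Not every gene that the rule took is printed in the report. It took up to 4 bound members of each list past adjusted p 0.05, strongest first, with up to 2 unbound members of depleted lists in alphabetical order. The homeotic and segmentation lists were included in any case. It also took the 5 strongest intron and 5 strongest intergenic peaks, and CG30020. Signal at a named gene is given as a multiple of the median IDR peak in the pooled list, and of the median of the matching peaks (strongest summit within 250 bp) in each replicate, so that the replicates' values show the error.

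Alternatives fixed in advance were promoter windows of 200 and 1000 bp, interval overlap in place of the summit, the stronger part of the IDR peaks, each replicate's 5048 strongest peaks alone, other overlap criteria, other backgrounds and other sequence windows. Chosen after seeing the data were 1 summit per merged interval, each summit counted for its nearest TSS only (divergent promoters), removal of chromosomes 4 and Y and of repeat-rich bins, removal of heavily covered bins, and all values over 100-kb bins. A bin counted as repeat-rich when at least 20% of it was annotated transposable element or at least 25% soft-masked, and as heavily covered when IDR peaks took at least 10% of its bases. Overlapping IDR intervals were merged, and merged intervals of at least 2000 bp were called broad.

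A transgene copy of CG30020 can add reads at that gene, so peaks there were located but not tested. The code was tested on simulated data. With a site planted in 5% of 5048 windows, the 6-mer test returned all 4 of its 6-mers and 0 others. A ribosomal protein list bound at 60% against 30% was called in 20 of 20 simulations of the list test, with 3 calls among 480 tests of unchanged lists. Each gene was bound independently in these simulations, so they do not cover lists whose members are neighbours. A motif consensus planted in the windows was found in 5.43% of them and in 0.139% of control windows. With 40% of 5048 simulated summits placed at promoters, 39.5% were found there. With 60.3% of 30000 peaks kept in place, 76.2% were found shared, against 24.4% with all peaks moved, so chance overlap is part of any shared percentage. A GC difference made as -0.5 was found as -0.484, and a difference of medians made as 0.3 as 0.327. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.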

Results

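The data were peak positions of GFP-tagged CG30020 protein in whole Drosophila embryos aged 0 to 24 h, from 1 group with 2 biological replicates (numbered 2 and 3). The product of CG30020 was profiled as a transcription factor, and the question the design addresses is where in the genome it is found. The authors' IDR set held 5048 peaks, which formed 4102 separate intervals and covered 2.60 Mb, or 1.89% of the 7 chromosomes. The relaxed lists of replicate 2, replicate 3 and the pooled libraries held 30000 peaks each. Sequencing depth per library is unknown from these lists. All coordinates are on dm6.

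The replicates shared most of their peaks, above all when only the strongest of each were compared. Of the 5048 strongest peaks of replicate 2, 84.5% overlapped a peak among the 5048 strongest of replicate 3, and 82.8% did in the other direction, where random placement gave 7.54% and 7.33% (permutation p = 0.002 each, the smallest that 1000 placements can give). Over all 30000 peaks the shared part was 66.8% of replicate 2 and 69.1% of replicate 3, against 24.9% and 24.3% by chance (permutation p = 0.002 each). Across the 5004 peaks that overlapped one to one, signal ranks gave Spearman's rho of 0.719 and log2 signal gave Pearson's r of 0.848 (permutation p = 1e-05 each). Peaks are not independent replicates, and the log2 ratio of replicate 3 to replicate 2 had an SD of 0.77 across those pairs.

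CG30020-eGFP was found above all at promoters. Within 500 bp of a TSS lay 72.3% of IDR summits, 5.33 times the 13.6% ± 0.480 (mean ± SD) of random placements, and the strongest peaks of replicate 2 and replicate 3 alone gave 71.2% and 73.9%. Coding exons were nearly empty, with 0.555% of summits against 13.9% at random (0.931% and 0.535% with the strongest peaks of replicates 2 and 3 alone). Introns held 16.1% against 39.3%, intergenic sequence 9.59% against 27.2%, 3' UTRs 0.634% against 4.48% and 5' UTRs 0.198% against 0.778%. Those 6 classes differed from random placement (adjusted permutation p = 0.000233 each, Benjamini-Hochberg over 7 classes), and non-coding exons, with 0.594% against 0.826%, did not pass (adjusted permutation p = 0.0690), though they were lower in 6 alternatives, replicate 2 alone among them (permutation p from 0.0008 to 0.0292). The classes are exclusive, so the high promoter share by itself lowers the shares of all others. Their deficits are therefore not separate results, and summits away from promoters were not tested among themselves. Coding exons fell to 0.0399 times the random share, further than introns (0.411 times) or intergenic sequence (0.353 times).

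**Figure D1:**
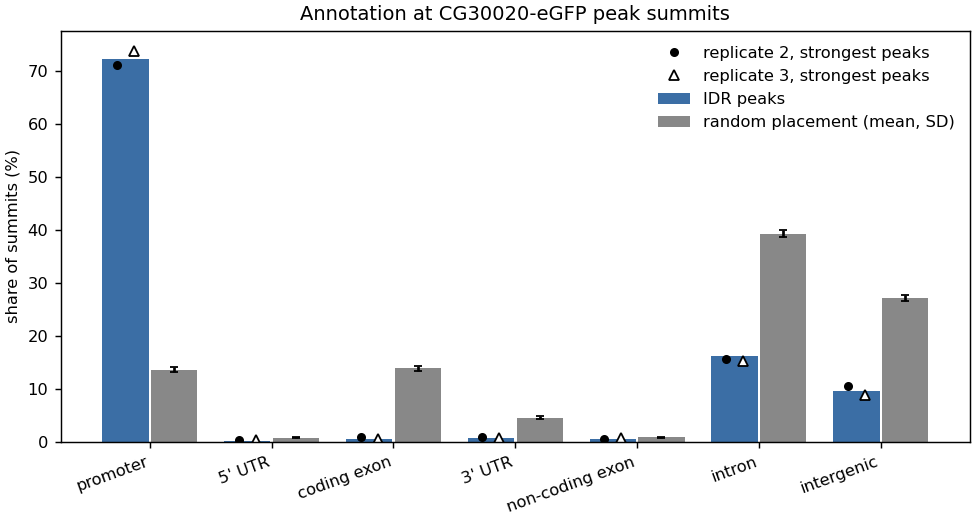
Share of IDR peak summits (%) in 7 exclusive annotation classes, beside the mean and SD of 10000 random placements, with points for the strongest peaks of each replicate alone. Promoters hold 72.3% of summits against 13.6% at random, and coding exons 0.555% against 13.9%.

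The promoter summits sat just upstream of the start site. Their median offset was -79 bp relative to the TSS, and 80.7% lay upstream of it. Promoter peaks were also stronger than the others, by 0.29 in median log2 signal in the IDR set, 0.31 in replicate 2 and 0.26 in replicate 3 (permutation p = 1e-05 each). Within the stronger part of the IDR peaks the difference was 0.14 (permutation p = 0.0042). Of the 505 strongest IDR peaks 85.1% were at promoters, and of the 504 weakest 62.9%. Of the relaxed pooled peaks outside the IDR set, 22.3% were at promoters, and the share in the IDR set lay above that of random draws from them (permutation p = 0.0002, the smallest that 10000 draws can give).

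Divergent promoters, where a gene on the opposite strand starts within 500 bp upstream, carried peaks more often than other promoters. Of 4134 protein-coding genes with such a neighbour 61.3% were bound, against 17.8% of the other 9811 (odds ratio 7.32, one-sided Fisher's exact test, log10 p = -543). The strongest peaks of replicate 2 alone gave 59.8% against 17.1%, and those of replicate 3 gave 61.4% against 17.9%. With 200 bp in place of 500 bp, for the window and for the distance that makes a gene divergent (1679 genes), the odds ratio was 3.66, and with 1000 bp it was 7.42. A neighbour's peak can count for both genes of a pair, and with each summit counted for its nearest TSS only, 35.7% of divergent and 16.6% of other genes were bound (odds ratio 2.80, Fisher's exact p = 1.22e-128, with pairs treated as independent genes). The share of bound genes also rose with the number of annotated TSSs, from 26.1% of genes with 1 TSS to 51.6% of genes with 5 or more.

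At the level of genes, 4284 of 13945 protein-coding genes (30.7%) had an IDR summit at a promoter. Genes for ribosomal proteins, mitochondrial ribosomal proteins, DNA replication, the proteasome, translation factors, oxidative phosphorylation, chromatin regulators of the Polycomb and Trithorax groups, and insulator factors were bound more often than other genes. Chemosensory, cuticle, haemocyte and fat body, ovary, testis, antimicrobial and segmentation genes were bound rarely. With Fisher's exact test and Benjamini-Hochberg adjustment over the 25 lists, 8 lists lay above the other genes, 7 below, and 10 did not pass. The test treats genes as independent, but some members of a list are neighbours, such as AttA and AttB on 2R. Neighbours can share a densely bound region or a summit, so the p-values of the lists can be too small. The strongest peaks of replicates 2 and 3 bound 4149 and 4294 genes, 3653 of them shared.

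Among cytoplasmic ribosomal protein genes 77 of 93 (82.8%) were bound, against 30.4% of other genes (odds ratio 11, adjusted exact p = 3.39e-24), and the replicates alone gave 77.4% and 83.9%. RpL5 on 2L had the strongest of these promoter peaks (22532732 to 22540943), at 41.9 times the median IDR peak in the pooled list, 54.7 times in replicate 2 and 28.3 times in replicate 3. RpL10 on 3L followed at 34.0 times, RpS3A on chromosome 4 at 32.7 times and RpS27A on 2L at 31.3 times. All these named genes lie in heavily covered bins. Of the genes of higher lists named here or below, so do mRpS7, eEF5, eIF4G1, eEF1delta, UQCR-11, Prosalpha6, Cdk1, CycD, RnrL, Utx, pho and Clamp. The multiples of these genes therefore cannot be assigned to the gene list rather than to the region. Outside heavily covered bins 68 of 83 cytoplasmic ribosomal protein genes (81.9%) were bound. Mitochondrial ribosomal protein genes were bound in 53 of 73 cases (72.6%, adjusted exact p = 1.21e-12). They were led by mRpS7 (46.3 times the median), mRpS5 (14.2 times), mRpL3 (9.70 times) and mRpS10 (7.05 times). Translation factors were bound in 31 of 52 cases (59.6%, adjusted exact p = 9.29e-05). The promoter of eEF5, an elongation factor, carried the strongest peak of the whole set, and eIF4G1, eIF4B and eEF1delta stood at 18.4, 15.8 and 14.7 times the median.

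Energy metabolism and protein turnover showed smaller excesses. Oxidative phosphorylation genes were bound in 45 of 86 cases (52.3%, odds ratio 2.49, adjusted exact p = 9.64e-05), including UQCR-11 of complex III at 40.9 times the median and the complex I genes ND-49, ND-AGGG and ND-MLRQ at 20.4, 20 and 16.1 times. Proteasome genes were bound in 24 of 48 cases (50%, odds ratio 2.26, adjusted exact p = 0.0115). Prosalpha6, a core particle subunit, led them at 36.8 times the median, followed by Prosbeta1 at 4.32, Rpn10 at 2.41 and Rpn7 at 2.10 times. In replicate 2 alone the proteasome share was 43.8% and no longer passed (adjusted exact p = 0.0582). With the stronger part of the IDR peaks neither oxidative phosphorylation nor proteasome genes passed, at 25.6% and 20.8% (adjusted exact p = 0.186 and 0.684).

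Genes of DNA replication and the cell cycle were bound in 25 of 35 cases (71.4%, odds ratio 5.67, adjusted exact p = 4.16e-06), but with the stronger part of the IDR peaks the share was 28.6% and did not pass (adjusted exact p = 0.201). Cdk1, the mitotic kinase, shared the promoter peak of mRpS7 on 2L (summit at 10386464), CycD on X stood at 9.69 times the median, and the ribonucleotide reductase genes RnrL and RnrS stood at 3.17 and 2.09 times. Polycomb and Trithorax group genes were bound in 19 of 28 cases (67.9%, adjusted exact p = 0.000251). Among them pho on chromosome 4 reached 35.2 times the median, mor 10.3, Utx 9.99 and E(z) 3.34 times. The insulator and promoter-binding factors had the highest share of any list, 15 of 17 genes (88.2%, odds ratio 17.0, adjusted exact p = 5.80e-06), and each replicate alone gave the same 88.2%. Clamp, a binder of GA repeats, was at 26.3 times the median, Cp190 at 4.98, Chro at 4.72 and M1BP at 2.48 times.

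Among the depleted lists the smallest p belonged to genes of the chemical senses. Of 230 chemosensory receptor and odorant-binding protein genes 3 were bound (1.3%, odds ratio 0.0291, adjusted exact p = 6.50e-31). These were Ir31a, whose peak interval is the one at RpS27A, Ir60b and Obp93a, and unbound members included Gr10a and Gr10b. Of 111 cuticle and chitin genes 3 were bound (2.70%, adjusted exact p = 5.06e-13), namely Cht11, Cht7 and Cht10 at 1.27, 1.08 and 0.865 times the median, while Cht12 and Cht2 were not. None of 18 haemocyte and fat body genes (crq and eater among them), 19 ovary and chorion genes (Cp15, Cp16) or 20 testis genes (aly, betaTub85D) was bound (adjusted exact p = 0.00358, 0.00358 and 0.00246). Of 23 genes for antimicrobial peptides and peptidoglycan recognition proteins, PGRP-LE alone was bound, and AttA and AttB were not (adjusted exact p = 0.00904). With the stronger part of the IDR peaks the haemocyte and fat body, ovary, testis, antimicrobial and segmentation lists did not pass (adjusted exact p from 0.101 to 0.186).

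Among the lists of patterning genes, only that of anterior-posterior segmentation was bound less often past the threshold. Of 31 anterior-posterior segmentation genes 2 were bound (6.45%, adjusted exact p = 0.00509). These were ci on chromosome 4, at 1.75 times the median, and nkd on 3L, at 1.25 times, whereas bcd and btd were not bound. None of the 10 genes in the homeotic list, which holds zen and zen2 besides genes such as abd-A and Abd-B, was bound. This small list nevertheless did not pass (adjusted exact p = 0.0553). Against genes with the same number of TSSs it did pass (37.6% expected, adjusted permutation p = 0.0211). Neural precursor genes (2 of 22, adjusted exact p = 0.0538), muscle structure genes (3 of 25, adjusted exact p = 0.0684) and differentiated neuron genes (3 of 23, adjusted exact p = 0.0949) did not pass either. The lists for the dorsal-ventral axis (4 of 24 bound), trachea and salivary gland (1 of 11), ecdysone response (3 of 21), the Notch pathway (8 of 21), heat shock proteins (9 of 24) and the circadian clock (3 of 11) had adjusted exact p from 0.191 to 1. With genes that have a relaxed pooled promoter peak as the background, 4 of the 8 higher lists still passed, those of both kinds of ribosomal proteins, translation factors and insulator factors. With the same background 2 of the 7 lower lists passed, cuticle and chemosensory genes. The haemocyte and fat body, ovary, testis and antimicrobial lists kept only 1 gene each with that background. They could not pass whatever the outcome, so this result does not speak against their depletion. Segmentation kept 7 genes, of which 28.6% were bound (adjusted exact p = 0.119). Muscle structure and ecdysone response genes also passed there as lower (27.3% each against 66.4%, adjusted exact p = 0.0338 each).

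**Figure D2:**
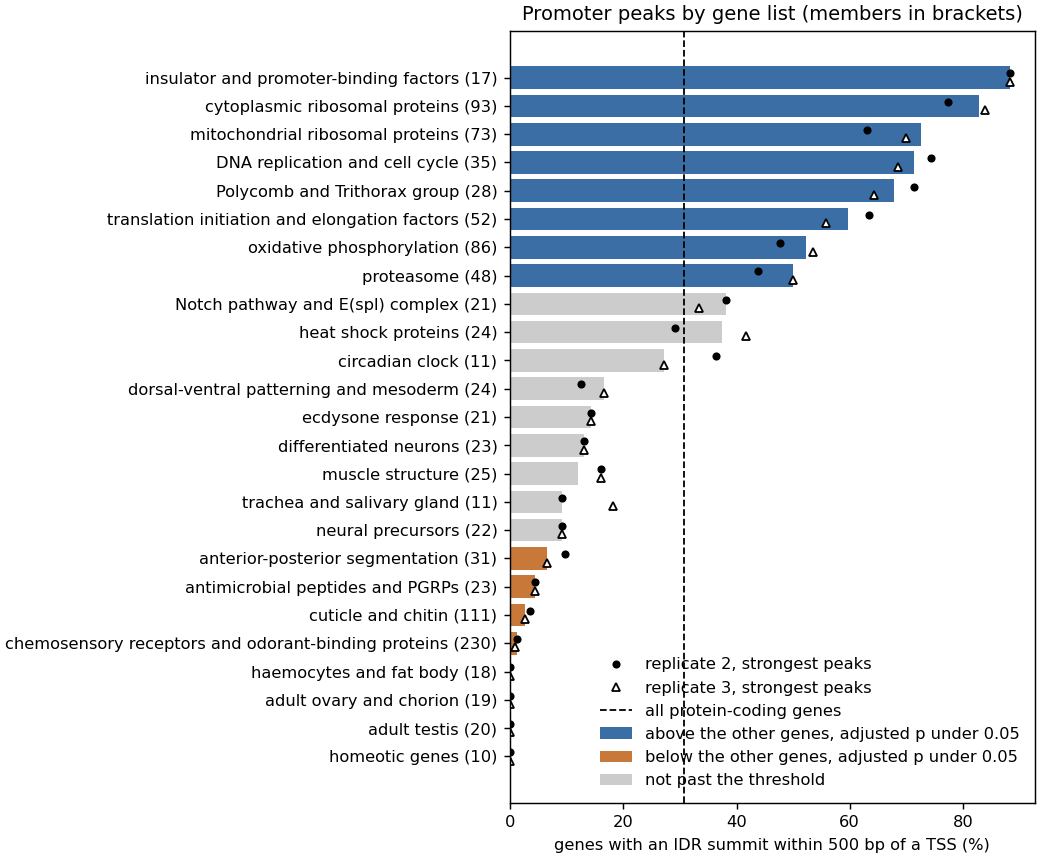
Share of protein-coding genes (%) with an IDR summit within 500 bp of a TSS in each of 25 gene lists, with list sizes in brackets, points for each replicate's strongest peaks alone and a dashed line at the 30.7% of all protein-coding genes. Insulator factors stand at 88.2% and cytoplasmic ribosomal proteins at 82.8%, and 4 lists stand at 0.

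Chromosome 4, the small and largely heterochromatic autosome, was the most densely occupied. It carried 195 peaks, 146 per Mb and 3.97 times the number expected from its length (adjusted permutation p = 0.000350 over 7 chromosomes), with 4.78 and 4.32 times in replicates 2 and 3 alone. Relative to the number of annotated TSSs the excess was 5.03 times. Broad peaks account for part of the count, and with 1 summit per merged interval it was 2.28 times. IDR peaks covered 16.9% of chromosome 4, against 1.29% to 2.5% of the 5 large arms, and 62 of its 80 protein-coding genes were bound (77.5%, against 30.5% elsewhere, Fisher's exact p = 7.22e-18). The heterochromatic Y chromosome had 4 peaks, 0.0318 times the number expected from its length (adjusted permutation p = 0.000350) and 0.169 times relative to TSS number. By length, replicates 2 and 3 alone gave 0.0478 and 0.0159 times on Y. The expected numbers allow neither for the dose of X and Y in embryos of mixed sex nor for mappability. Deficits on X and Y therefore do not measure occupancy alone. The large arms differed little, from 0.864 times on 3R to 1.11 times on 2R, and the slight excess on 2L and 2R was absent relative to TSS number (0.978 and 0.995 times). By TSS number 3L showed a slight excess (1.08 times, adjusted permutation p = 0.0164), and the deficit on X, 0.920 times by length (adjusted permutation p = 0.0114), did not pass (0.961 times, adjusted permutation p = 0.313).

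The strongest peaks lay on chromosome 4, near centromeres and in a few gene-rich blocks. All of the 20 strongest were at promoters. Of these, 10 lay on 2R (9 of them in repeat-rich bins), 5 on chromosome 4, 2 on 2L, 2 on 3L and 1 on 3R. The strongest, at eEF5 on 2R (24056543 to 24064505, summit 38 bp from the TSS), had 93.1 times the median signal in the pooled list, 97.2 times in replicate 2 and 75.5 times in replicate 3. Near the centromere of 2R followed lncRNA:CR42646 (58.6 times), CG17683 (56.4), gus (51.9), CG17883 (50.4), CG3107 (49.3), CG17486 (47.6), CG17528 (46.7), Nipped-A (45.9), which encodes a subunit of histone acetyltransferase complexes, and d4 (43.9). On chromosome 4 these included anne (63.6 times), 4E-T (47.7), Eph (44.2) and PlexA (44.1), the last a semaphorin receptor. MED21, a Mediator subunit, and Spf30, a splicing factor, stood on 3L at 55.5 and 49.8 times, mRpS7 and ClpP on 2L at 46.3 and 44.3 times, and Tim17b on 3R at 44 times. Replicate 2 gave a higher multiple than replicate 3 at each of the 20, for example 69.1 against 31.7 times at Spf30.

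Away from promoters, the 5 strongest intron summits lay in d4 (1692 bp from the nearest TSS), in stw, which held 2 of them, in nAChRalpha4 on 3L and in Cadps on chromosome 4, at 10.2 to 42.4 times the median. The 5 strongest intergenic summits had their nearest TSS at CG41128 on 3R (39452 bp away), Haspin on 2R (1312 bp), mRpS5 on 3L (1031 bp), snoRNA:CD-24 on chromosome 4 (2126 bp) and ey, the eyeless gene, on chromosome 4 (746 bp). They stood at 15.1 to 39.3 times the median. At the tagged gene itself, CG30020 (FBgn0050020) on 2R (10886810 to 10893191, plus strand), an IDR summit lay 22 bp from the TSS. It ranked 1748 of 5048 at 1.3 times the median, and replicate lists 2 and 3 had summits 18 and 22 bp from the TSS. Further IDR summits outside the gene, at 10885166 and 10894329, were nearest to CG18004 and cag.

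**Figure D3:**
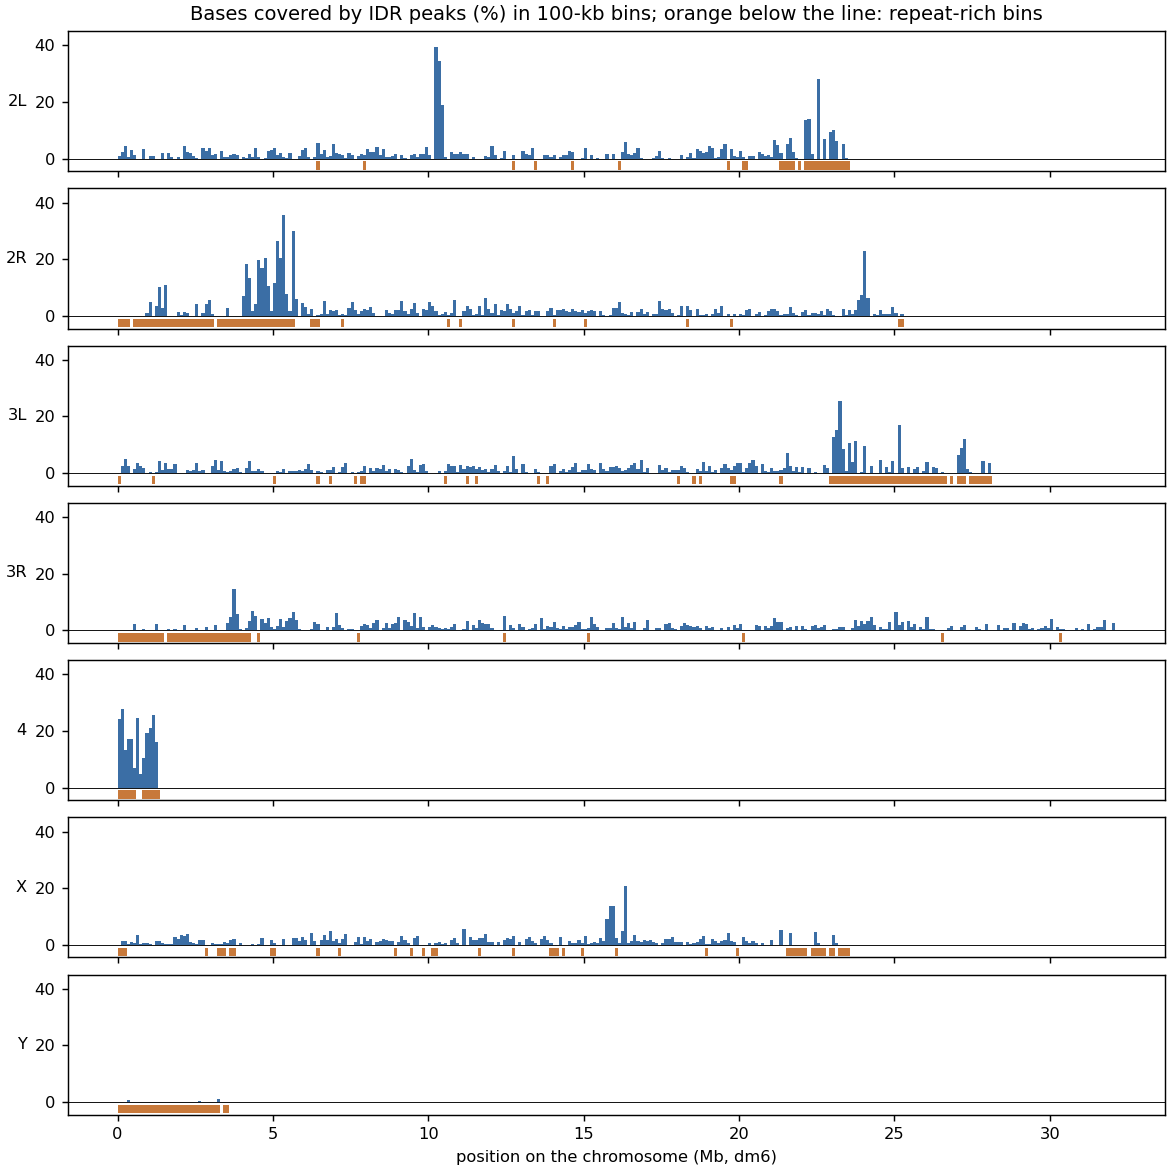
Percent of bases covered by IDR peaks in 100-kb bins along the 7 chromosomes (position in Mb), with repeat-rich bins marked in orange under the axis. High coverage is seen on 2L at 10.2 to 10.5 Mb, on proximal 2L, 2R and 3L, over chromosome 4 and in blocks of distal 2R and X, and the Y chromosome is nearly empty.

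The bases at the summits were rich in A and T and carried several core-promoter elements. GC content was 33.6% within 50 bp of the summit and 41.7% at 300 bp, a difference of -8.09 ± 0.213 percentage points (SE over 5048 peaks, permutation p = 1e-05). Promoter summits were at 34.0% and windows at the same offset from unbound TSSs at 41.7%. The DNA replication-related element, TATCGATA, the site of the factor Dref, was within 50 bp of 5.84% of summits and in 1.07% of flanks (adjusted exact p = 3.51e-41, McNemar test). In replicates 2 and 3 alone it was at 5.39% and 5.94% of summits. Motif 1, GGTCACAC, the site of M1BP, was at 2.93% against 0.753%, Ohler motif 6 at 2.42% against 0.971%, and Ohler motif 7 at 7.96% against 3.94% (adjusted exact p = 4.06e-16, 3.76e-08 and 1.10e-16). These 4 elements were also more frequent at promoter summits than at unbound promoters, for example 7.10% against 1.81% for the DNA replication-related element (adjusted exact p = 5.05e-28, Fisher's test) and 3.84% against 0.959% for Motif 1 (adjusted exact p = 1.38e-15). At summits away from promoters the DNA replication-related element was still above its flank, 2.57% against 0.50% (adjusted exact p = 5.98e-05), and Motif 1, at 0.572% against 0.357%, did not differ (adjusted exact p = 0.908).

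The TATA-like consensus was at 18.5% of summits against 10.5% of flanks (adjusted exact p = 2.77e-29), and at promoter summits it was above unbound promoters, 18.7% against 12.1% (adjusted exact p = 2.49e-14). The initiator was at 23.7% against 21.6% (adjusted exact p = 0.0172), but against unbound promoters it was lower, 22.9% against 27.6% (adjusted exact p = 1.01e-05). Rare insulator sites were above the flank, with the BEAF-32 dual core at 0.258% against 0.0198% (adjusted exact p = 0.00407) and the Su(Hw) core at 0.396% against 0.0990% (adjusted exact p = 0.00741), and neither passed against unbound promoters or with the stronger part of the IDR peaks (adjusted exact p = 0.376 and 0.299). The BEAF-32 dual core did not pass in replicate 2 alone (adjusted exact p = 0.340), nor did the Su(Hw) core with the flank at 1000 bp or a wider window (adjusted exact p = 0.624 and 0.427). The CA repeat CACACACA and GAGAGAG were less frequent, with CACACACA at 0.654% against 3.19% (adjusted exact p = 1.34e-20) and the GAGA element at 0.693% against 2.54% (adjusted exact p = 2.64e-13). The Mad-Medea site of Dpp signalling was at 2.12% against 4.62% (adjusted exact p = 1.48e-11), but it is rich in G and C, and base composition was not separated from it. The Zelda site, the CAGCTG E-box and the Twist-type E-box were also lower (adjusted exact p = 0.00438, 0.0159 and 0.0208), and none of these 3 passed in replicate 3 alone. Sites of Pho, CTCF, Grainyhead, AP-1 and STAT and the A tract did not pass against the flank (adjusted exact p from 0.304 to 1), but the A tract was higher with the flank at 1000 bp and with the wider window (adjusted exact p = 0.00818 and 0.0227).

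Without assuming any motif, 441 of the strand-collapsed 6-mers were more frequent at summits and 934 less frequent (exact McNemar tests, adjusted exact p under 0.05). The smallest p belonged to TATCGA, at 16.3% of summits against 5.35% of flanks (adjusted exact p = 2.06e-67), and CGATAG and ATCGAT, at 11.5% and 13.2% of summits, were also among the 10 smallest. The others near the top were strings of A and T such as ATTTAA (30.4% against 15.5%) and AAATAT (34.3% against 19.3%). Among the depleted 6-mers the smallest p belonged to CTCCTC (0.773% against 4.40%), followed by GCCGCC (1.53% against 5.37%).

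**Figure D4:**
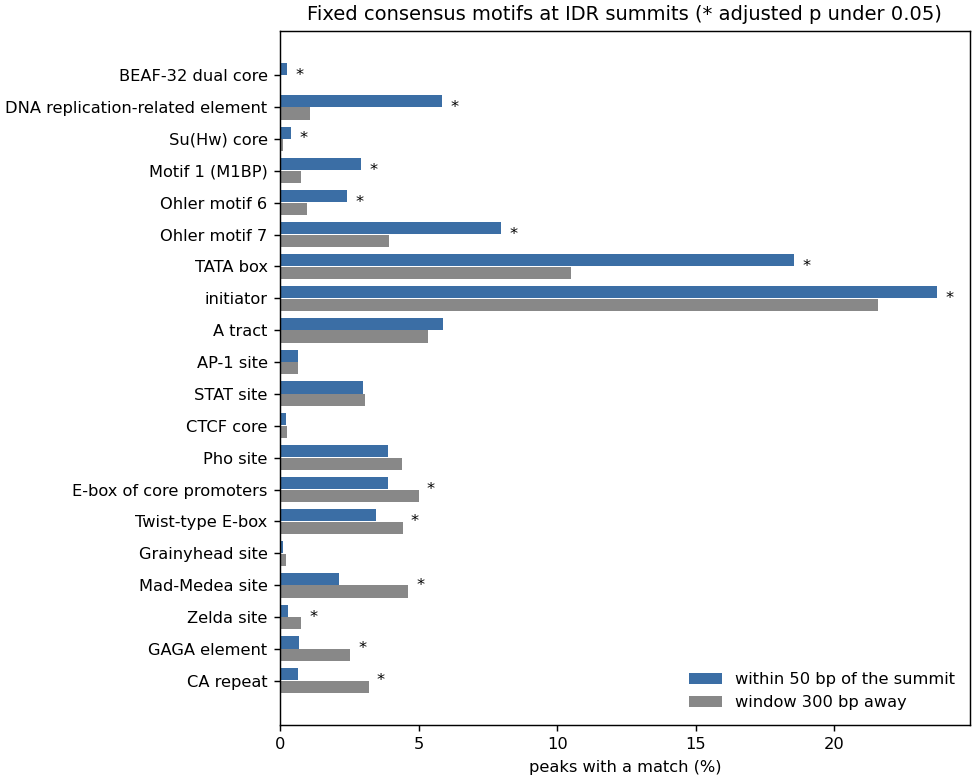
Percent of 5048 IDR peaks with a match to each of 20 fixed consensus motifs within 50 bp of the summit and in a window 300 bp away, ordered by the ratio of these shares, with a star at adjusted p under 0.05. The DNA replication-related element is at 5.84% against 1.07%, and the CA repeat at 0.654% against 3.19%.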

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

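Of the main results (overlap, rank agreement, promoter share, classes, arms, list counts, divergent promoters, signal, motif and 6-mer counts and GC content), 73 recomputations fixed before the data were examined and 36 chosen after seeing the data kept their direction and side of the threshold, or their count within 1.5 times, and 7 did not. The promoter share ranged from 59.4% with a window of 200 bp to 79.2% without chromosomes 4 and Y and repeat-rich bins. The pooled list's 5048 strongest summits are the IDR summits themselves, so that alternative tests nothing and is left out of these numbers. With the stronger part of the IDR peaks, 5 lists lay above and 2 below the other genes, without oxidative phosphorylation (25.6%), proteasome (20.8%) and replication genes (28.6%); the cause was not tested. With genes that have a relaxed promoter peak as background, 4 lay above and 4 below, from fewer genes tested, and the antimicrobial list turned to 100% on 1 gene. Permutation within strata of TSS number gave 12 lists below, adding homeotic, neural precursor, neuron, muscle and ecdysone genes. Motifs below the flank numbered 6, and 3 to 4 with a single replicate's peaks; the cause was not tested. Against unbound promoters 5 motifs were higher, and the initiator (22.9%) and the Twist-type E-box (3.43%) changed direction; only promoter peaks enter there. By TSS number, 2L and 2R fell to 0.978 and 0.995 times the expected peaks. Depth is unknown, and with 2 replicates leaving out 1 leaves no spread.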

Other observations

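The tests in this part were chosen after the results were seen, except the comparison with unbound promoters and the background of genes with a relaxed peak, which were fixed before the data were examined. The design has 1 group, so no biological explanation was tested.

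Signal was concentrated in few places. Of 1379 bins of 100 kb, 43 had at least 10% of their bases under IDR peaks, and these 3.13% of the genome held 31.2% of the covered bases. Chromosome 4 supplied 11 of them, repeat-rich bins on the large arms 25, and gene-rich sequence 7. The widest gene-rich block, 2L from 10200001 to 10500000, was covered to 31% (22.2% and 29.1% with the strongest peaks of replicates 2 and 3 alone), and 80 of the 97 protein-coding genes starting there were bound, among them Prosalpha6, eEF1delta, Utx, RnrL, ClpP, Cdk1, mRpS7 and RpS27A. The other gene-rich blocks were on 2R at 24.0 to 24.1 Mb, around eEF5, and on X at 15.8 to 16.0 Mb, with CycD and PGRP-LE, and at 16.3 to 16.4 Mb. Of 182 merged intervals of at least 2000 bp, 78.6% lay on chromosome 4 or in repeat-rich bins, against 11% of narrower ones (Fisher's exact p = 3.32e-92). A promoter window was touched by 88.5% of the broad and 75.1% of the narrower intervals, which a wide interval does more readily. Of the bases in broad intervals 36.5% were promoter.

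Outside chromosomes 4 and Y, bins with at least 20% transposable element sequence were covered to 5.72% on average and the other bins to 1.55% (permutation p = 0.00151 over 1327 rotations of the bins, the smallest these can give). Defined by soft-masking alone, repeat-rich bins did not pass (2.56% against 1.61%, permutation p = 0.0994). Defined by either measure they passed (2.75% against 1.55%, permutation p = 0.0120), but not with the strongest peaks of replicate 3 alone (permutation p = 0.0813). Over all transposon-rich bins 32.9% of 389 genes were bound, against 30.4% of 13476 other genes, a difference that did not pass (Fisher's exact p = 0.289). Non-coding genes were seldom near a summit: 7.02% of 3261 ncRNA genes, 5.20% of 269 snoRNA genes and none of 99 rRNA genes. How reads from repeated genes were handled is not given. A lack of summits at such genes, those for rRNA among them, therefore does not show that the protein was absent there.

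The first pattern weighed is the broad peaks of the 43 heavily covered bins. If reads of repeated sequence had piled up there, summits might lie in transposable elements more often than random positions of the same bins. Of the summits 13.7% did, against 25.2% at random (permutation p = 0.0002), so summits were not concentrated in annotated elements. The test used 1 base per peak, not the broad intervals, and how reads that map to several places were handled is not given. Inflation of the intervals by repeats therefore stays open. A single library does not account for the broad peaks: bins that replicate 3 alone covered to at least 10% were covered to 15.7% in replicate 2 (1.35% elsewhere), and bins chosen in replicate 2 to 19.1% in replicate 3 (1.36% elsewhere). Gene density alone does not account for the gene-rich blocks, since of 158 bins outside repeat-rich sequence with at least 33 TSSs, the fewest in any such block, 4.43% were heavily covered. A contribution of gene density stays open. The median coverage of those 158 bins was 2.66%, against 0.946% over all bins, and the minimum of 33 TSSs was taken from the covered bins themselves. Copy number, low mappability in the control and recovery by the antibody without the tag stay open, as no control track or untagged embryos were analysed here. A candidate explanation is a link to chromatin bound by HP1a, whose textbook sites include chromosome 4, pericentromeric sequence and cytological region 31, but no HP1a map was used here. The gene-rich blocks on distal 2R and on X lie outside these named sites, and the heterochromatic Y chromosome had only 4 peaks.

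The second pattern is the DNA replication-related element at summits. Low GC content alone would raise all 6-mers of the same bases alike, but TATCGA, which the element contains, rose 3.03-fold over the flank where the other 6-mers of its composition had a median of 1.23-fold, and ATCGAT rose 2.90-fold. Nor was it as common at every promoter, since windows at the same offset from unbound TSSs held it in 1.81% against 7.10%. The element, with CGATAG, is read by Dref and BEAF-32, so CG30020-eGFP may be recovered together with such factors or may read part of the site itself. No value here separates these, and most summits lack an exact match.

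The third pattern is the higher share of bound promoters in 8 of the gene lists. Recovery of any heavily transcribed locus would include tRNA genes, of which 2.76% had a summit within 500 bp, against 30.7% of protein-coding genes. These shares do not decide the question. RNA polymerase III transcribes tRNA genes, how reads from repeated genes were handled is unknown, and the 30.7% covers all protein-coding genes, whatever their expression. An equal gain at any promoter with some signal would leave the lists level with other genes that have a relaxed peak, of which 66.0% to 66.2% had an IDR peak. Cytoplasmic ribosomal proteins were at 90.6%, mitochondrial ones at 86.9%, translation factors at 86.1% and insulator factors at 100% (adjusted exact p = 8.13e-06, 0.00283, 0.0381 and 0.0203). An equal gain stays open for oxidative phosphorylation (71.4%), proteasome (82.8%), replication (80.6%) and Polycomb and Trithorax genes (79.2%), which did not pass (adjusted exact p from 0.171 to 0.505). The IDR summits are the strongest pooled summits, so passing here shows only that signal at a list's promoters was more often high. A gain that grows with promoter openness or activity is not tested by this comparison, for any list. Open chromatin or transcription by RNA polymerase II at these promoters stays open, since no expression or accessibility data were used here, and it may account for some or all of the pattern.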
